A study of Rattus norvegicus with 10 samples.

How the data were processed

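Libraries were made from total RNA of rat hippocampal cultures with an integrity number above 9, per the labels' protocols, from 5 vehicle and 5 TTX samples. The submitters' processing notes name HISAT2 2.1.0, StringTie, DESeq2 and the rat build rn6. Which tool counted reads, and whether strand was used, is not given in the sources used here, so overlapping or antisense genes and near-identical copies are uncertain.

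The authors deposited 1 table with whole-number counts per gene and library, which were used as deposited. Per the file headers the same table holds FPKM values, which were used only to estimate transcript length. The deposited log2 fold changes and their p-values with false discovery rates are named as the authors' and come from DESeq2, per the submitters' processing notes. A second deposited table lists 54 raised secreted factors, whose values equal those in the first. The table has 14608 lines, and 241 gene names occur more than once. Repeats were collapsed, which removed 254 lines and left 14354 genes. No gene has fewer than 10 counts summed over the libraries. Among counts from 1 to 20, 57.0% are even, and 482 values are 1 against 1626 that are 2, so both mates of a pair may have been counted.

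Of the gene names, 13527 match a current symbol in a rat gene table of assembly GRCr8, 627 only a synonym and 200 neither. That assembly differs from the authors' build, so gene positions are not used here.

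Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). The filter left 13088 genes and 1266 were not tested. SE is the absolute log2 fold change over the square root of the F statistic. A test against 1.5-fold used glmTreat. CPM values used the TMM library sizes. Depth was 52254261 to 84921962 counts per library, so low genes limit precision, and SEs and p-values cover the spread between these samples. The biological coefficient of variation was 7.59%. The authors' deposited table calls 9374 genes (4708 higher, 4666 lower). Of the calls made here, 9144 are also called there, all in the same direction.

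Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, over lists with at least 5 tested members. Camera compares a list with all other genes, whereas fry asks whether its genes move one way on balance and compares it with no other genes. Before the data were examined, 29 lists were fixed, together with the design, the settings to be varied and the rule for named genes. The erythroid list had 1 tested gene, Slc4a1 (log2 fold change -0.69, adjusted p = 0.0655), and was left out of list tests. Another 4 lists were chosen after seeing the data. Of the members of fixed lists, 710 matched by symbol and 4 by synonym, 7 were the same gene as another member, and 27 have no entry.

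Named genes were, among called genes with a mean of at least 1 CPM, an official-looking symbol and no overlap between the groups, the 8 with the largest rise and the 8 with the largest fall, then Il33, the 3 members of each list with the smallest p and the 5 genes of the secreted table with the smallest p. This gave 99 genes, of which some are not reported here. Other genes named, such as list members that moved against their list, were chosen after their values were seen.

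The pipeline was tested on simulated data for TTX against vehicle with 13088 genes, 200 of them changed. It recovered 50% of genes changed 1.2-fold, 72% at 1.5-fold, 90% at 2-fold and 98% at 4-fold. In the data 9221 genes were called, which makes the adjusted p cut-off less strict, so these rates hold only for the simulated setting. The simulated changes were few and equally often up and down, so TMM scaling with many changed genes was not tested. Of 160 calls, 5 were unchanged genes. The 1 raised list was called and none of the 30 unchanged lists. Simulated genes were independent of each other, so this does not test lists whose members vary together. All replicate pairs were compared, and their counts differed beyond sampling noise (chi-square per gene of 10.2 to 23.9), so no pair was merged as 1 library. This does not show that the libraries came from separate cultures.

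Alternatives were other scalings (RLE, library totals, upper quartile), no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, a replicate block and leaving out each library. Added after seeing the data were thinning to the smallest library total, thinning every count to 50%, and removing a trend with transcript length, which could be estimated for 98.6% of tested genes. Of 126 splits of the libraries into 5 and 5, 100 were drawn with a fixed seed, the real one included.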

Results

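RNA was sequenced from mixed cultures of neurons and glia grown from the hippocampus of Sprague-Dawley rat embryos. At 19 days in vitro the cultures received 1 µM tetrodotoxin (TTX), a blocker of voltage-gated sodium channels that silences action potentials, or vehicle, for 24 h. Each group holds 5 libraries, numbered 1 to 5. The count table gave 52254261 to 77757538 counts per vehicle library and 58785925 to 84921962 per TTX library, with medians of 65711502 and 64637781. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

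The comparison asked how blocking activity changes transcripts in these cultures, and the series title names interleukin-33 from astrocytes and homeostatic synaptic plasticity. After TTX, 26 of 27 immediate-early genes and 20 of 22 late activity-regulated genes were lower, with median log2 fold changes of -1.54 and -2.18. Neither list passed camera with an estimated correlation (adjusted p = 0.0604 for each). Npas4, a neuronal transcription factor induced by calcium entry, fell from 92.6 ± 8.61 to 0.0987 ± 0.0676 CPM (counts scaled to library size, SD, n = 5 in each group). Bdnf, which encodes a neurotrophin, fell from 453 ± 37.1 to 15.1 ± 0.823 CPM, 30.1-fold lower. Of the genes tested, 19 of 23 for glycolysis, 20 of 23 for cholesterol synthesis and 15 of 19 for cell division fell, and 11 of 15 oligodendrocyte and 8 of 11 precursor markers rose, although as lists none of these 5 passed camera with an estimated correlation (adjusted p = 0.239 to 0.622). Of other glial and ependymal markers, 12 of 20 for astrocytes and 8 of 11 for ependymal and choroid plexus cells rose, and 13 of 17 for microglia did not pass (medians of 0.22, 0.34 and 0.37). Il33 rose 1.47-fold. Of 13088 genes tested, 4638 were higher and 4583 lower with TTX by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These are 70.5% of the genes, split nearly evenly. A list with many members called in each direction is therefore not set apart by its counts. Tested against a 1.5-fold change, 700 genes were higher and 1104 lower. In 7505 genes (57.3% of those tested) the ranges of the groups did not overlap, where chance gives 0.794%. The first principal component held 69.7% of the variance and separated the groups, and the second held 4.65%.

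The largest rises were in Htr1a, a serotonin receptor, with a log2 fold change of 4.50 ± 0.231 (SE), and in Itih3, at 3.36 ± 0.171. Mdga1, a membrane protein that binds neuroligins, rose from 10.6 ± 0.399 to 84.4 ± 3.90 CPM. Grid2ip, R3hdml, Sprr1a, Tmem114 and Wnt4, a secreted Wnt ligand, rose by 2.84 to 3.32 on the log2 scale. Among the largest falls, Gprc5a, an orphan receptor, went from 69.0 ± 5.29 to 1.23 ± 0.355 CPM. Cyp26b1, an enzyme that breaks down retinoic acid, fell from 173 ± 16.8 to 6.14 ± 0.884 CPM. Perm1, Pax1, Serpinb2 and Scin had log2 fold changes of -4.73, -5.28, -6.38 and -7.05. Scin had no count in 4 of the 5 TTX libraries and 8 counts in TTX replicate 1. Without that replicate every TTX library was at 0, and the fitted log2 fold change of Scin moved to -10.74. Pax1 and Serpinb2 also had libraries at 0, and how reads were assigned to genes is not given in the sources used here, so the size of these 3 falls is uncertain. Il33 rose in all 5 TTX libraries, from 44.2 to 53.8 CPM with vehicle to 69.0 to 74.3 CPM with TTX (log2 fold change 0.56 ± 0.0464 SE, adjusted p = 6.38e-08). Its change did not pass the test against 1.5-fold (adjusted p = 1), and 1325 genes called higher had a larger log2 fold change. Il1rl1, which encodes the receptor of interleukin-33, had 57 counts over all 10 libraries and was below the filter. Also below it were Tnf, with 3 to 7 counts per vehicle library and 9 to 36 per TTX library, and Il1b, with 0 to 5 and 5 to 14, both named after their values were seen.

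**Figure D1:**
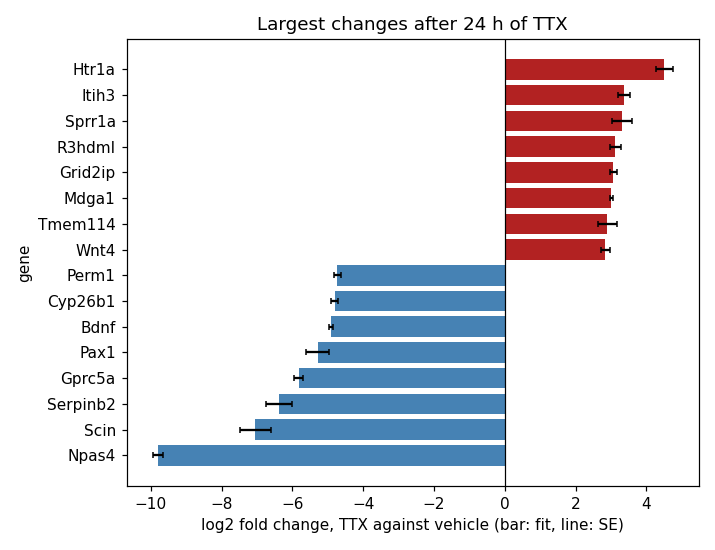
Log2 fold change (horizontal axis, TTX against vehicle, n = 5 in each group) of the 8 genes with the largest rise and the 8 with the largest fall; bars show the fitted value and lines the SE. Npas4 reaches -9.80 and Htr1a 4.50.

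Of 27 immediate-early genes, which are induced within minutes of activity, 26 fell and 1, Klf10, rose (26 lower and 1 higher adjusted over the list alone). The median log2 fold change was -1.54. Nr4a1, a nuclear receptor, fell from 87.3 ± 2.14 to 10.4 ± 0.692 CPM, and Per1, a clock gene, was 2.92-fold lower. The camera test placed the list below other genes (adjusted p = 6.19e-11), with adjusted p = 0.0604 with an estimated correlation. Of 22 late activity-regulated genes 20 fell and 2, Nptx1 and Mfap3l, rose, with the same counts adjusted over the list alone. Nrn1, a secreted plasticity factor, was 7.59-fold lower and Pam, an enzyme that amidates peptides, 5.04-fold lower. The median was -2.18 (camera adjusted p = 9.12e-09, and adjusted p = 0.0604 with an estimated correlation). Of 22 regulators of homeostatic scaling 12 fell, 7 rose and 3 did not pass, with the same counts adjusted over the list alone. Nptx2, a pentraxin that clusters AMPA receptors, was 5.79-fold lower and Plk2, a kinase of synaptic down-scaling, 2.71-fold lower. This list did not pass camera (adjusted p = 0.132). Its members Arc, Bdnf, Homer1, Nptx1, Nptx2 and Plk2 also stand in the activity lists above, so it is not separate evidence.

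Synaptic gene lists moved in both directions, as did genes as a whole (70.5% called, 4638 higher and 4583 lower). Of 22 genes of GABA synthesis, transport and receptors, 12 fell and 5 rose (12 and 6 adjusted over the list alone). Gad1 and Gad2, which make GABA, were 2.02-fold and 1.91-fold lower. Of 40 glutamate receptor and scaffold genes 16 rose and 18 fell, also adjusted over the list alone. Grm2, a presynaptic metabotropic receptor, rose 3.99-fold, Homer3, a postsynaptic scaffold, rose 2.75-fold, and Grip1 was 1.92-fold lower. Their median was -0.05 and their mean 0.06. Of 34 genes of presynaptic release 13 rose and 16 fell (14 and 16 adjusted over the list alone). Sv2b and Vamp1, vesicle proteins, rose 2.18-fold and 1.65-fold, and Sv2c was 2.85-fold lower. Of 50 ion channel genes, most of them voltage-gated, 23 rose and 20 fell, also adjusted over the list alone. The potassium channel Kcnc4 rose from 28.8 ± 0.746 to 120.3 ± 3.32 CPM, whereas Kcnj4 was 3.96-fold lower and the pacemaker channel Hcn4 4.80-fold lower. The median of the channel list was 0.09, its mean -0.07 and its direction up by camera but down by fry, a test of whether genes move one way on balance. None of these 4 lists passed camera (adjusted p = 0.238, 0.911, 0.642 and 0.911 in the order given).

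Of 23 glycolysis genes 19 fell, 2 rose and 2 did not pass (20 lower and 2 higher adjusted over the list alone), with a median of -0.46. Slc2a1, a glucose transporter, was 3.53-fold lower and Ldha, which makes lactate, fell from 1563 ± 63.8 to 731 ± 32.0 CPM. Pdk1 was 2.09-fold lower. Camera called this list (adjusted p = 2.75e-06), with adjusted p = 0.319 with an estimated correlation. Of 23 genes of cholesterol synthesis 20 fell, 1 rose and 2 did not pass (20 lower and 2 higher adjusted over the list alone), with a median of -0.44. Stard4, a sterol carrier, was 4.88-fold lower, and Hsd17b7 and Mvd, enzymes of the pathway, were 2.80-fold and 1.79-fold lower. Camera called the list (adjusted p = 4.51e-06), with adjusted p = 0.239 with an estimated correlation. Of 29 genes of oxidative phosphorylation 7 rose, 8 fell and 14 did not pass, with the same counts adjusted over the list alone. Ppargc1a, a regulator of mitochondrial genes, was 1.40-fold lower, Cycs 1.21-fold and Ndufv2 1.17-fold lower (camera adjusted p = 0.642). Of 34 ribosomal protein genes 1 rose and 15 fell (1 and 13 adjusted over the list alone). Rpl4, Rps14 and Rpl27a were 1.12-fold to 1.16-fold lower (camera adjusted p = 0.198). Of 29 genes of the unfolded protein and heat-shock responses 10 rose and 15 fell, also adjusted over the list alone. Atf4, a stress transcription factor, and its targets Chac1 and Ddit3 were 3.02-fold, 5.35-fold and 2.72-fold lower (camera adjusted p = 0.121).

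Secreted factors were the subject of the authors' deposited table of 54 raised genes. All 54 rose, also adjusted over the list alone, and in 49 the groups did not overlap. Because the authors chose these genes on the same libraries, their direction is not independent evidence. Il33 is among the 54, so this limit holds for its rise too. Tested against a 1.5-fold change, 11 of the 54 passed. Csf1, a growth factor for microglia, rose from 42.8 ± 1.46 to 86.6 ± 1.59 CPM, 2.02-fold. Mgp, a matrix protein that binds bone morphogenetic proteins, rose 2.59-fold. Cp, the copper carrier ceruloplasmin, rose 1.88-fold, Gpc1, a glypican, 1.51-fold and Olfm2 1.37-fold.

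**Figure D2:**
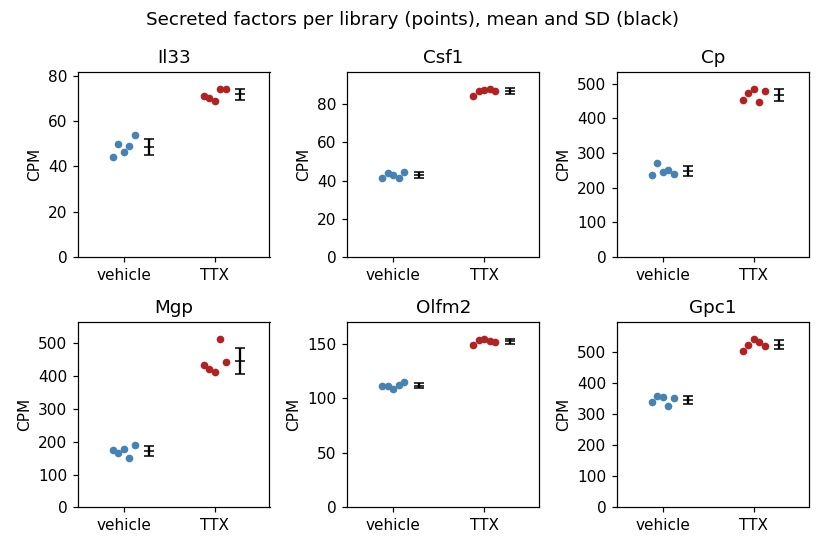
CPM (vertical axis, from 0) of Il33 and 5 other genes in each of 5 vehicle and 5 TTX libraries. Il33 and the others are from the authors' deposited table of secreted factors. Points are libraries and black marks the mean with SD. Every TTX library lies above every vehicle library, and Csf1 goes from 42.8 to 86.6 CPM.

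Of 28 astrocyte-secreted synaptic factors 15 rose, 7 fell and 6 did not pass, also adjusted over the list alone, and 4 members stand in the authors' table. Cntf and Tgfb3, secreted signals, rose 2.76-fold and 2.44-fold, and Cst3, a protease inhibitor, 1.48-fold. Gdnf, Vegfa and Lif, chosen after their values were seen, were 7.87-fold, 6.32-fold and 2.90-fold lower. The median was 0.14, the mean -0.05 and camera's direction up (adjusted p = 0.198). Of 19 cytokines and chemokines 8 rose and 6 fell, also adjusted over the list alone. Csf1 was among those that rose. Cx3cl1, a neuronal chemokine, was 1.96-fold lower and Ccl2 2.75-fold lower (camera adjusted p = 0.599). Of 37 growth factor genes 13 rose and 15 fell, also adjusted over the list alone. Gdf10 rose 3.13-fold, whereas Igfbp4 was 2.40-fold and Hbegf 2.25-fold lower (camera adjusted p = 0.431). Of 35 matrix and perineuronal net genes 10 rose and 17 fell, also adjusted over the list alone. Acan, the main proteoglycan of perineuronal nets, was 13.5-fold lower and Adamts1, a protease of such proteoglycans, 2.60-fold lower, and Vcan rose 1.84-fold (camera adjusted p = 0.272).

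Markers of cell types were measured in the same libraries. Of 18 pan-neuronal markers 7 rose, 5 fell and 6 did not pass, also adjusted over the list alone, with a median of 0.07. Nefh and Celf4 rose 2.17-fold and 1.47-fold, and Gap43 was 1.27-fold lower (camera adjusted p = 0.384). Of 16 excitatory markers 10 rose and 3 fell, also adjusted over the list alone. The transcription factors Neurod2 and Tbr1 rose 2.67-fold and 2.65-fold, and Slc17a6 was 1.91-fold lower. Their list missed the camera threshold (adjusted p = 0.0548, and adjusted p = 0.600 with an estimated correlation). It passed without vehicle replicate 4 (adjusted p = 0.0492), vehicle replicate 5 (adjusted p = 0.0381), TTX replicate 3 (adjusted p = 0.0469) or TTX replicate 4 (adjusted p = 0.0433), and with no low-count filter (adjusted p = 0.0460). Of 17 inhibitory markers 4 rose and 7 fell, also adjusted over the list alone, among them Npy, 1.42-fold lower. Their median was 0.06 and mean 0.01, and camera's direction was down (adjusted p = 0.565).

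Of 20 astrocyte markers 12 rose, 3 fell and 5 did not pass, also adjusted over the list alone. Gfap, an intermediate filament, rose 1.81-fold to 9702 ± 198 CPM, Gja1, a gap junction protein, 1.84-fold and Aldoc 1.49-fold. The list had a camera adjusted p = 0.0730, and adjusted p = 0.0439 without TTX replicate 3. Of 32 reactive astrocyte genes 15 rose and 12 fell, also adjusted over the list alone. Cp rose, whereas Ptgs2, also a member of the late activity-regulated list, was 4.46-fold and Aspg 2.68-fold lower. The median was 0.06 and camera's direction up, and the mean was -0.11 and fry's direction down (camera adjusted p = 0.772). Of 15 oligodendrocyte markers 11 rose and none fell, also adjusted over the list alone, with a median of 0.40. Cnp, a myelin gene, rose 1.51-fold and Bcas1 1.56-fold (camera adjusted p = 0.0170, and adjusted p = 0.585 with an estimated correlation). Of 11 precursor markers 8 rose and 1, Pdgfra, fell, also adjusted over the list alone. Olig1 and Olig2, transcription factors of the lineage, rose 2.17-fold and 1.79-fold, and Gpr17, a receptor of differentiating cells, 2.43-fold. This list passed camera (adjusted p = 0.0478, and adjusted p = 0.622 with an estimated correlation). The call ended without vehicle replicate 4 (adjusted p = 0.0673), TTX replicate 1 (adjusted p = 0.0559) or TTX replicate 2 (adjusted p = 0.0568). It also ended with a filter of 1 CPM in 5 libraries (adjusted p = 0.0544) and with a replicate block (adjusted p = 0.0559). Of 17 microglial markers 3 rose, 1 fell and 13 did not pass (1 and 1 adjusted over the list alone). P2ry12 rose 3.40-fold and Ptprc 1.63-fold (camera adjusted p = 0.416 for the list). Ptprc had an adjusted p = 0.0533 without TTX replicate 5, adjusted p = 0.0528 by limma-voom and adjusted p = 0.0520 with a replicate block. The mean log2 level of these markers differed widely between TTX libraries, from 0.64 below the group mean in replicate 1 to 0.67 above it in replicate 5.

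Of 19 proliferation markers 15 fell, 1 (Aurkb) rose and 3 did not pass, also adjusted over the list alone, with a median of -1.09. Top2a, Ccnb2 and Rrm2, genes of DNA replication and mitosis, were 3.91-fold, 3.23-fold and 2.92-fold lower (camera adjusted p = 0.000106, and adjusted p = 0.585 with an estimated correlation). Of 17 vascular, mural and meningeal markers 2 rose and 6 fell, also adjusted over the list alone. The matrix genes Dcn and Lum were 2.72-fold and 2.31-fold lower, and Myh11 rose 1.38-fold (camera adjusted p = 0.515). Of 11 ependymal and choroid plexus markers 8 rose and none fell, also adjusted over the list alone. Clic6, Rsph1 and Ccdc153 rose by 0.59, 0.48 and 0.43 on the log2 scale (camera adjusted p = 0.132). Of 24 interferon-response genes 15 rose and 2, Irf7 and Tap1, fell, also adjusted over the list alone, with a median of 0.45. Mx2, Gbp2 and Irf1 rose 2.44-fold, 1.76-fold and 1.47-fold (camera adjusted p = 0.0170, and adjusted p = 0.599 with an estimated correlation). Against the group mean, the mean log2 level of the interferon genes ran from -0.13 in TTX replicate 3 to 0.21 in TTX replicate 2. Interferon genes and microglial markers did not always vary together between libraries. Their levels were 0.11 and -0.32 in vehicle replicate 5, in that order, and 0.12 and 0.67 in TTX replicate 5.

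Of 28 fixed lists 8 passed camera with its preset correlation of 0.01, and none passed with an estimated correlation. In 52 of 100 splits of the libraries, the real one included, 8 or more lists passed, so the number of lists past that test does not by itself set TTX apart from other groupings.

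**Figure D3:**
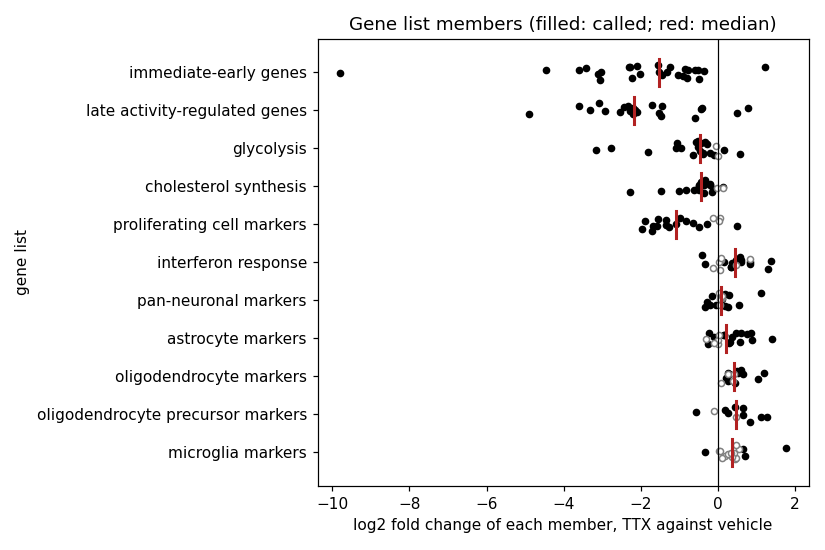
Log2 fold change (horizontal axis, TTX against vehicle) of each tested member of 11 gene lists (vertical axis); filled points passed the edgeR test, open points did not, and red lines mark medians. The median is -2.18 for late activity-regulated genes and 0.47 for oligodendrocyte precursor markers.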

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

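The tests of proliferation and oligodendrocyte-lineage markers were chosen after the result was seen. Those of list medians, depth, read pairs and transcript length were chosen after the calls were seen but before their own outcome. Of 198 groups of 5 libraries checked for a library far from the rest, 11 stood out, and about 1 in 20 does so by chance.

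TTX replicate 5 stood apart on the second principal component, at 25.8 against -10.9 to -1.64 in the other TTX libraries. In TTX replicate 1, Scin was at 0.0940 CPM against 0 in the others. TTX replicate 3 was high for Cyp26b1 (7.67 against 5.39 to 5.99 CPM), Sv2c (5.83 against 4.85 to 5.10 CPM) and Top2a (18.7 against 16.0 to 16.6 CPM). TTX replicate 5 was low for Kcnc4 (114.5 against 120.7 to 123.0 CPM) and Ddit3 (19.0 against 20.4 to 20.9 CPM). Vehicle replicate 4 was low for Gprc5a (59.9 against 69.7 to 72.9 CPM) and Nptx2 (382 against 413 to 419 CPM). Vehicle replicate 3 was high for Hbegf (34.2 against 30.2 to 30.8 CPM) and vehicle replicate 1 for Ccnb2 (33.1 against 27.4 to 28.3 CPM).

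The first pattern is the large number of genes called between TTX and vehicle. Of 100 splits of the libraries only 1, the real one, gave as many calls (9221 against at most 1 in another split). The same held for genes higher (4638) and genes lower (4583), so a chance division of these libraries is argued against. Every other split mixes TTX and vehicle libraries, which raises the spread and lowers its calls, so the size of the gap carries no weight. The splits cannot tell TTX from another difference between the 2 groups of libraries. A difference in depth is argued against by 8978 calls kept after thinning to the smallest library, read pairs counted as 2 reads by 8607 kept at 50% of the counts, and a trend with transcript length by 8950 kept after its removal. Fewer neurons as a whole, as the cause of the genes lower by more than 1.5-fold, are argued against by pan-neuronal markers. Their median log2 fold change was 0.074, with quartiles of -0.04 and 0.18. These markers would not show the loss of a neuron subtype, which was not tested. The TTX treatment, which the design names, stays open.

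For gene lists chance cannot be excluded by their number. In 52 of 100 splits, the real one included, 8 or more lists passed camera, against 8 for the real split and 16 in the highest other. With 5 and 5 libraries no other split holds equal numbers of TTX and vehicle libraries on each side, and the immediate-early list was called in all 100. For each of the 8 lists that passed, which the real split itself picked, the absolute median log2 fold change was as large in only 1 split, the real one. The highest in another split was 1.202. The same held for lists that did not pass, among them the GABA, homeostatic scaling and astrocyte marker lists. Every other split mixes TTX and vehicle libraries, which shrinks most medians, so this comparison does not set the 8 lists apart. In 1 of 100 splits, the real one, the 54 secreted factors gave 54 calls in the real split and at most 0 in another, but they were selected on the real split, so this comparison excludes nothing.

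The second pattern is the lower level of proliferation markers. A fall in astrocyte transcripts as a whole is argued against by a median of 0.22 for their markers (lower quartile -0.02). These markers do not count cells, so fewer astrocytes with more transcript each, or fewer dividing astrocytes, cannot be told apart. Fewer oligodendrocyte precursors cannot be told apart from lower expression: their markers had a median of 0.47 (lower quartile 0.21), but Pdgfra fell by 0.57 on the log2 scale while Gpr17, a gene of differentiating cells, rose. Fewer fibroblast-like or vascular cells cannot be told apart either, since the median of those markers was -0.029 with quartiles of -0.62 and 0.17 while Dcn and Lum fell. A lower rate of division in cultures treated with TTX may account for the pattern and was not tested.

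The third pattern is the higher level of oligodendrocyte-lineage markers. A smaller share of neuronal RNA cannot be told apart from a change in these cells. The median log2 fold change of pan-neuronal markers was 0.074, but a small fall in a large share would be hidden there. Astrocyte, ependymal and microglial markers had medians of 0.22, 0.34 and 0.37, though 13 of 17 microglial markers did not pass, and vascular, mural and meningeal markers were at -0.03. Whether there were more such cells or more transcript per cell was not tested.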

How the results depend on the processing

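The thinned, halved and length-corrected fits were chosen after seeing the data. Genes called higher ranged from 4346 to 4910 and genes lower from 4307 to 4670 over scalings, filters, tools and added fits. Against 1.5-fold the counts were 700 and 1104, since that test asks for a larger change. Leaving out each library gave 4405 to 4548 genes higher, 4462 to 4555 lower, 54 secreted factors each time, 7 to 10 lists, and a log2 fold change of 0.52 to 0.60 for Il33. Lists past camera were 8, against 0 with an estimated correlation and 23 by fry, which tests another question. Under fry the ion channel list turned direction with a call (adjusted p = 0.0143), and the reactive astrocyte list turned without one (adjusted p = 0.468). Over the named genes 1761 comparisons kept direction and call and 3 lost the call, all for Ptprc. Over the lists 414 were unchanged in call, 20 gained it and 13 lost it.

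The replicate numbers did not pair the libraries: same-numbered libraries had correlations of -0.058 to 0.011, and 0 of 5 correlated best with their own number. With a replicate block 4572 genes were higher and 4563 lower, 54 secreted factors were higher, 7 lists passed without the precursor list (adjusted p = 0.0559), Ptprc was not called (adjusted p = 0.0520) and Il33 had a log2 fold change of 0.56. Depth limits low genes, such as Il1rl1, which was below the filter.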

Other observations

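The 4 lists in this part were chosen after seeing the data, so their p-values are descriptive and are not evidence for the lists. Adjusted p-values here are over these 4 lists alone. Some members, such as Crh, were already counted among the activity-regulated genes. Of 19 neuropeptide genes 14 fell, 4 rose and 1 did not pass (15 lower adjusted over the list alone). Adcyap1, which encodes PACAP, had a log2 fold change of -4.38 ± 0.082 (SE), Crh -3.33 ± 0.10 and Pdyn, which encodes dynorphins, -1.79 ± 0.072, while Gal, which encodes galanin, rose by 0.99 ± 0.056 (camera adjusted p = 0.000863, and adjusted p = 0.0913 with an estimated correlation). Of 15 feedback regulators of MAP kinase signalling 12 fell and 2 rose, also adjusted over the list alone. Spry4 was at -2.74 ± 0.043 and the phosphatase Dusp4 at -2.57 ± 0.045, and Dusp14 rose by 0.70 ± 0.054 (camera adjusted p = 0.000354, and adjusted p = 0.0913 with an estimated correlation).

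Receptors of neuromodulators were split, as genes were as a whole, with 14 of 39 higher and 14 lower (15 and 14 adjusted over the list alone). Oprl1, the nociceptin receptor, rose by 2.28 ± 0.049 and Sstr2 by 1.29 ± 0.043, whereas Drd1, a dopamine receptor, was at -2.31 ± 0.10 and Sstr1 at -1.81 ± 0.078 (camera adjusted p = 0.745). Of 17 genes of retinoic acid handling 6 rose and 9 fell (7 and 9 adjusted over the list alone). Rara, a retinoic acid receptor, was at -1.57 ± 0.048 and Rxrg, a retinoid receptor, rose by 0.67 ± 0.057 (camera adjusted p = 0.680).

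Some genes had no counts in single libraries of either group while other libraries had many, and a count of 0 in these genes cannot be read as absence of the transcript. Aldh18a1 had 0 counts in TTX replicate 2 against 2539 to 3707 elsewhere, Htr7 had 0 in TTX replicate 1 against 246 to 700, and Tmco3 had 0 in vehicle replicate 2 against 1160 to 4545.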
